A study of Homo sapiens with 8 samples.

How the data were processed

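Polyadenylated RNA from AB8/13 cells was sequenced in 8 libraries, 4 from cells that received a non-targeting shRNA and 4 from cells that received an shRNA against ATOH8. Per the labels' protocols, the cells were expanded at 33 °C, moved to 37 °C for 5 days to differentiate, and transfected with a lipid reagent, and only RNA with an integrity number above 7.0 went into directional libraries. The deposited table holds whole numbers per gene, taken here as raw read counts, with 1 column per library and versioned Ensembl gene identifiers. Per the submitters' processing notes, hg19, FastQC, STAR, featureCounts and DESeq2 were named for this work. Their versions, the gene annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. In 46 rows counts jumped at least 5-fold between libraries of a group, as estimated assignment of ambiguous reads would give, so it is not settled whether the values are plain featureCounts counts.

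The authors' counts were used as deposited. Of 60609 rows in the deposited table, 1 row with a missing cell and no value above 0 was left out, as were 44 copies of pseudoautosomal genes on the Y chromosome with 0 counts, which left 60564 genes. Symbols came from a table of gene names for 60295 of them and from GENCODE release 29 for 250, and 19 stayed without a symbol. Where several rows carried a symbol, the row with the most counts kept it. GENCODE release 29 describes GRCh38 and not hg19, so it served for names, gene types, the chromosome of a gene and transcript sequences, and no coordinates are printed. The total count per library ran from 21108695 to 27109043.

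Genes with enough counts were chosen with edgeR's filterByExpr by group, libraries were scaled by TMM, and the groups were compared with edgeR's quasi-likelihood F test with robust dispersion estimates, in edgeR 4.0.16 and limma 3.58.1 under R 4.3.3. Fold changes are log2 of ATOH8 knockdown against control, their standard errors (SE) were derived from the F statistic, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method, with 0.05 as the threshold. CPM values are counts scaled to library size by TMM, given as mean ± SD over the 4 libraries of a group. The design text calls the libraries of a group biological replicates and does not say whether they came from separate cultures or transfections or whether both groups came from one cell stock, so p-values measure the spread between these libraries, which may be technical in part. Neither the sequence nor the number of shRNAs against ATOH8 is stated.

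Before the data were examined, 27 gene lists, the tests, the alternatives and a rule for the genes to name were fixed. Lists with at least 5 tested members were tested two-sided with camera at an inter-gene correlation of 0.01, adjusted over the 26 lists tested, and again with a correlation estimated per list. The rule named ATOH8, then the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 2, no overlap between the groups and a symbol, without pseudogenes, and then per list up to 3 rising and 3 falling members with the smallest adjusted p. For lists that were not called, not every gene the rule allowed was printed, and a few genes that the rule named are not reported here. Genes that other parts of the text name were chosen after their values were seen, which is said there except for NPHS1 and ISY1-RAB43. For ATOH8 alone an exact permutation test over 70 assignments of the libraries was added.

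The fit was tested on simulated counts with the means, trended dispersions and library sizes of this comparison. In them 200 genes were changed by known folds and 16682 genes passed the filter, whereas 51.1% of tested genes changed in the data. All 50 genes changed 2-fold and 48 of 50 changed 1.3-fold were recovered, and 4.7% of the 232 calls were unchanged genes. A simulated list of 30 genes moved together was called and 0 of 20 random lists were. Genes were simulated independently of each other, so this does not test camera on lists whose members correlate. In the data the estimated correlation was 0.543 for interferon-stimulated genes. The 12 pairs of libraries within a group were compared for duplicates, and the chi-square per gene ran from 1.95 to 4.48, so none agreed within sampling noise.

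Alternatives were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts beyond 1 count in total, a filter of at least 1 CPM in 4 libraries, the replicate number as a block, the omission of each library in turn, and for lists an estimated correlation, fry in place of camera and the removal of members shared between lists. Sequence words in 3′ untranslated regions (UTRs) and shifts of whole chromosomes were examined in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, after the fold changes had been seen. The fold change, limited to a log2 size of 2, was regressed on the presence of each word of 7 bases found in at least 50 genes, with UTR length, UTR GC content and mean expression in the model. In simulated data, a word made to lower its genes by a fixed amount ranked 1 of 16247 words, and a chromosome given a shift was found.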

Results

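Gene expression was measured by RNA sequencing in AB8/13, a conditionally immortalised human podocyte line that divides at 33 °C and differentiates at 37 °C. Podocytes are the epithelial cells that cover the glomerular capillaries of the kidney, and ATOH8 encodes a basic helix-loop-helix transcription factor. The control group held 4 libraries from cells given a non-targeting shRNA, and the ATOH8 knockdown group held 4 libraries from cells given an shRNA against ATOH8. Total counts ran from 21108695 to 27109043 per library, and mitochondrially encoded genes took 4.37% to 5.09% of them. NPHS1 (nephrin), a marker of mature podocytes, had 0 to 2 counts in control and 2 to 6 in knockdown libraries, too few to test.

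The comparison asked how expression differs between cells given the shRNA against ATOH8 and cells given the control shRNA. ATOH8 (ENSG00000168874.13, chromosome 2) was lower in each of the 4 knockdown libraries than in any control library. Its level was 5.83 ± 0.66 CPM in control and 2.43 ± 0.33 CPM in knockdown libraries (SD, n = 4), which left 41.7% of the control level. The counts behind these values were 175, 160, 122 and 128 in control and 51, 71, 61 and 53 in knockdown libraries. The log2 fold change was -1.26 (SE 0.127, edgeR quasi-likelihood test, adjusted p = 1.78e-09), and the two-sided exact permutation test gave p = 0.0286, the smallest value that 4 libraries against 4 allow.

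Beyond ATOH8, the groups differed in much of the transcriptome, mostly by small amounts. Of 16884 genes tested, 4253 were higher and 4372 lower in ATOH8 knockdown, together 51.1%, with a median absolute log2 change of 0.29 among them. A change of at least 2-fold was found for 757 genes, of which 555 rose and 202 fell. More genes had at least 1 count in each knockdown library (25426 to 26071) than in any control library (24154 to 25081). The cause of that difference was not tested. The groups did not overlap for 7697 genes (45.6%), against 2.86% by chance. Spread within groups was low, with a common biological coefficient of variation of 3.75%, and the first principal component held 54.9% of the variance of the 1000 most variable genes and separated the groups. The count of genes changed at least 2-fold depends on the filter on low counts, with 1481 genes without a filter and 476 with a stricter one.

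**Figure D1:**
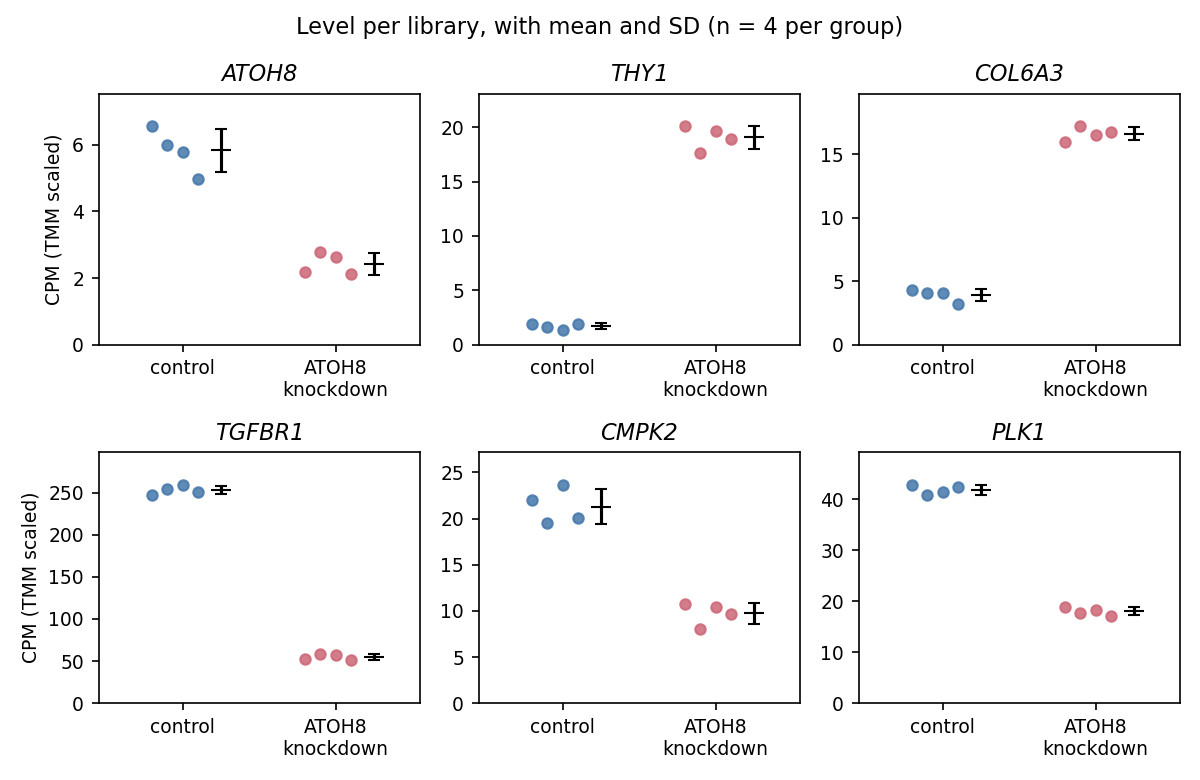
TMM-scaled CPM (vertical axes, starting at 0) of 6 genes in each control library (blue) and each ATOH8 knockdown library (red), with the mean and SD of the 4 libraries of a group in black. ATOH8 averaged 5.83 CPM in control and 2.43 CPM in knockdown libraries, and in none of the 6 genes did the groups overlap.

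The largest rises included a claudin, surface proteins and a laminin chain, and no class of genes was tested among them. CLDN11, a tight junction claudin, went from 0.335 ± 0.211 to 12.2 ± 1.23 CPM (SD, n = 4), a log2 fold change of 5.19 (SE 0.229, edgeR adjusted p = 6.94e-11). THY1, the surface glycoprotein CD90, rose 11.1-fold from 1.69 ± 0.264 to 19.1 ± 1.07 CPM (log2 3.48, SE 0.098, edgeR adjusted p = 1.87e-21). NGFR, the low-affinity neurotrophin receptor, rose 7.22-fold, and LAMA4, the laminin alpha-4 chain, rose 6.28-fold. MEG3, an imprinted noncoding RNA of chromosome 14, whose genes had a median log2 change of 0.16, rose 5.68-fold, RGS4, a regulator of G-protein signalling, 5.25-fold, and ANK1, an ankyrin of the membrane skeleton, 4.74-fold. The other 3 of the 10 largest rises are less certain. H4C14 (log2 2.90, SE 0.457) is a histone gene with near-identical copies. NECTIN3-AS1 (log2 2.28, SE 0.116) is an antisense transcript, and the strand setting of the counting is not given in the sources used here. FAM220A (log2 2.63, SE 0.888, edgeR adjusted p = 0.0475) had 251, 3, 20 and 0 counts in the control libraries, its log2 change ran from 2.21 to 5.72 when 1 library was left out, and its call was lost when any 1 library other than control replicate 1 was left out (edgeR adjusted p = 0.0837 to 0.105), under the replicate block (0.124), without a filter (0.0868) and by DESeq2 (0.146).

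Among the largest falls were a growth factor receptor, inflammation-linked genes and a prostaglandin transporter, and no class of genes was tested among them. TGFBR1 (ENSG00000106799.13), the type I receptor for TGF-beta, had the smallest p of them and fell from 253 ± 5.09 to 54.9 ± 3.64 CPM (log2 -2.20, SE 0.039, edgeR adjusted p = 2.32e-26). Its annotated 3′ UTR holds 4 copies of the heptamer GTCAATT, but no other of the 10 largest falls with a searched 3′ UTR holds it. In the regression described above, genes with this heptamer had fold changes -0.13 (log2) from those of genes without it. That value is adjusted for UTR length, UTR GC content and expression. SAGSIN1 fell from 13.9 ± 4.65 to 0.335 ± 0.229 CPM (log2 -5.33, SE 0.54, edgeR adjusted p = 0.000199). UGT1A6, which conjugates phenols with glucuronic acid, had a log2 change of -3.31 (SE 0.082), and its row shares exons with the other genes of the UGT1A locus. CLDN2, a claudin that forms cation channels, fell with a log2 change of -2.39 (SE 0.132). The inflammation-linked genes UBD, a ubiquitin-like modifier (log2 -2.19, SE 0.113), and CCL20, a chemokine (log2 -1.96, SE 0.071), fell, as did THBD, which encodes thrombomodulin (log2 -2.10, SE 0.162), and SLCO2A1, the prostaglandin transporter (log2 -1.87, SE 0.093). ADAMTSL4 (log2 -2.15, SE 0.089) and IGFN1 (log2 -1.96, SE 0.140) complete the 10.

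Interferon-stimulated genes and inflammatory genes fell together. Of 29 tested interferon-stimulated genes, 27 fell, 1 rose and 1 did not pass the test, with a median log2 change of -0.88. IFIH1, a sensor of double-stranded RNA, fell by 1.16 on the log2 scale (SE 0.056), and CMPK2, an interferon-induced kinase of mitochondria, from 21.3 ± 1.92 to 9.73 ± 1.17 CPM. The member that rose was IRF9 (log2 0.12, SE 0.045, edgeR adjusted p = 0.0327), whose groups overlapped and whose call was lost in 6 of the 8 fits that left out 1 library. The camera test called the list lower (adjusted p = 1.66e-16), a call lost at adjusted p = 0.104 with an estimated correlation. Of 26 NF-kB and inflammatory genes, 21 fell, 2 rose and 3 did not pass, with a median of -0.54 (camera adjusted p = 2.03e-22, and adjusted p = 0.0336 with an estimated correlation). VCAM1, an adhesion molecule for leukocytes, fell from 60.6 ± 3.15 to 22.5 ± 0.867 CPM (log2 -1.43, SE 0.048), and CXCL5, a chemokine for neutrophils, from 349 ± 7.31 to 178 ± 10.3 CPM (log2 -0.97, SE 0.036). IL1B (log2 0.28, SE 0.055) and TNFAIP3 (log2 0.12, SE 0.033) rose. Adjusted over the list alone, the counts of both lists were the same.

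Most of the listed cell cycle genes fell, and most of the p53 target and apoptosis genes rose. Of 34 cell cycle genes, 23 fell, 5 rose and 6 did not pass, with a median log2 change of -0.43 (camera adjusted p = 3.67e-14, but adjusted p = 0.064 with an estimated correlation). The counts adjusted over the list alone were 23 and 6. The falls with the smallest adjusted p were those of the cyclin gene CCNB1, from 117 ± 4.71 to 61.5 ± 1.41 CPM (log2 -0.93, SE 0.037), and the mitotic kinase genes PLK1 (log2 -1.21, SE 0.048) and AURKA (log2 -1.03, SE 0.043). The members that rose included MCM5, a subunit of the replicative helicase (log2 0.30, SE 0.036), TYMS, which makes thymidylate (log2 0.23, SE 0.033), and E2F1, a transcription factor of S-phase genes (log2 0.26, SE 0.039). Of 25 p53 target and apoptosis genes, 18 rose, 3 fell and 4 did not pass, with a median of 0.35 (camera adjusted p = 5.28e-11, and adjusted p = 0.0439 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 985 ± 22.4 to 1468 ± 35.7 CPM (log2 0.58, SE 0.031), TP53I3 rose by 0.82 (SE 0.042) on the log2 scale, and the DNA repair gene DDB2 by 0.60 (SE 0.034). MCL1, a survival factor (log2 -0.45, SE 0.031), and the caspase gene CASP8 (log2 -0.30, SE 0.045) fell. Of 7 replication-dependent histone genes, 6 rose and 1 did not pass, among them H4C8 (log2 1.97, SE 0.136), H1-2 (log2 0.90, SE 0.085) and H2BC12 (log2 0.75, SE 0.073). That list was called higher by camera (adjusted p = 0.000103, but adjusted p = 0.0978 with an estimated correlation). Transcripts of these histones mostly lack a poly(A) tail, and the libraries were made from polyadenylated RNA. The counts of the p53 and histone lists were the same when adjusted over the list alone.

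Most of the listed matrix and mesenchymal genes were higher. Of 30 basement membrane and extracellular matrix genes, 22 rose, 6 fell and 2 did not pass (median log2 0.17, camera adjusted p = 1.91e-08, but adjusted p = 0.104 with an estimated correlation), and adjusted over the list alone 22 rose and 7 fell. The chains COL6A3 of collagen VI, from 3.92 ± 0.478 to 16.6 ± 0.515 CPM (log2 2.08, SE 0.085), LAMA4 and the basement membrane linker NID2 (log2 1.40, SE 0.080) had the smallest adjusted p of the rises. COL4A4 (log2 -0.50, SE 0.069) and COL4A5 (log2 -0.25, SE 0.047), chains of the glomerular basement membrane, and the protease inhibitor TIMP1 (log2 -0.22, SE 0.038) fell. Of 19 epithelial-mesenchymal transition and myofibroblast genes, 12 rose, 3 fell and 4 did not pass (median 0.35, camera adjusted p = 4.53e-05, and adjusted p = 0.0328 with an estimated correlation). By adjusted p the first of the rises were THY1, the receptor tyrosine kinase AXL (log2 0.43, SE 0.031) and the intermediate filament VIM (log2 0.37, SE 0.034), while ZEB2 (log2 -0.29, SE 0.035), CDH11 (log2 -0.32, SE 0.043) and MYH10 (log2 -0.17, SE 0.033) fell. The call of this list was lost without the members it shares with other lists (adjusted p = 0.0992).

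Marker lists of other cell types differed in their calls, and only members with enough counts were tested. Of 10 mesangial and pericyte markers, 5 rose, 1 fell and 4 did not pass (camera adjusted p = 3.52e-08, and adjusted p = 0.0246 with an estimated correlation), with THY1, the proteoglycan CSPG4 (22.8 ± 0.554 to 83.4 ± 6.95 CPM, log2 1.87) and NOTCH3 (log2 1.37, SE 0.132) rising and RGS5 (log2 -0.39, SE 0.096) falling. Only 7 of the listed glomerular endothelial markers had enough counts to test. Of these, 5 rose and 2 did not pass (camera adjusted p = 0.00335, but adjusted p = 0.064 with an estimated correlation), and adjusted over the list alone 6 rose. The receptor gene TIE1 (log2 2.69, SE 0.149) reached 6.77 ± 0.335 CPM in knockdown libraries, and SOX17 (log2 0.82, SE 0.111) and EHD3 (log2 0.50, SE 0.052) rose. ROBO4, another endothelial receptor, named here after its values were seen, had a log2 change of -0.01 (SE 0.084, edgeR adjusted p = 0.966). Only 4 of the leukocyte markers had enough counts, too few for a list test, and of these ITGAM (log2 2.56, SE 0.32, at 1.14 CPM in knockdown libraries) and CD68 (log2 0.42, SE 0.040) rose. Of 14 parietal epithelial and epithelial markers, 7 rose, among them the keratin genes KRT19 (log2 0.83, SE 0.039) and KRT8 (log2 0.46, SE 0.033), and 4 fell, and of 7 proximal tubule markers 2 rose and 2 fell, among them the water channel AQP1 (log2 -2.18, SE 0.163). Neither list was called by camera (adjusted p = 0.186 and 0.579), though the parietal list was without knockdown replicate 2 (0.0354), and the tubule markers had a median of 0.16 and a mean of -0.13. Counts of the transition, mesangial, leukocyte, parietal and tubule lists were the same when adjusted over the list alone.

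Podocyte genes went both ways. Of 20 tested podocyte and slit diaphragm genes, 10 rose, 5 fell and 5 did not pass, with a median log2 change of 0.23, and camera did not call the list (adjusted p = 0.186). INF2, a formin mutated in inherited focal segmental glomerulosclerosis, rose from 119 ± 4.14 to 147 ± 1.77 CPM (log2 0.31, SE 0.033), and the actin-associated gene SYNPO rose from 17.2 ± 1.14 to 24.9 ± 2.06 CPM (log2 0.53, SE 0.062). MYO1E, a myosin of the podocyte (log2 0.26, SE 0.031), also rose. KIRREL1 (log2 -0.36, SE 0.031), a slit diaphragm protein, PLA2R1 (log2 -0.65, SE 0.060), the antigen of membranous nephropathy, and CD2AP (log2 -0.26, SE 0.040), an adaptor of the slit diaphragm, fell. Of 31 actin cytoskeleton and focal adhesion genes, 17 rose, 4 fell and 10 did not pass (median 0.13, camera adjusted p = 0.00578, but adjusted p = 0.104 with an estimated correlation). The adhesion genes PXN (log2 0.39, SE 0.032), ITGA5 (log2 0.37, SE 0.032) and ACTN1 (log2 0.35, SE 0.032) rose, and CNN3 (log2 -0.21, SE 0.030), ITGAV (log2 -0.20, SE 0.031) and ITGB1 (log2 -0.14, SE 0.032) fell. Adjusted over the list alone, the counts of both lists were the same.

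**Figure D2:**
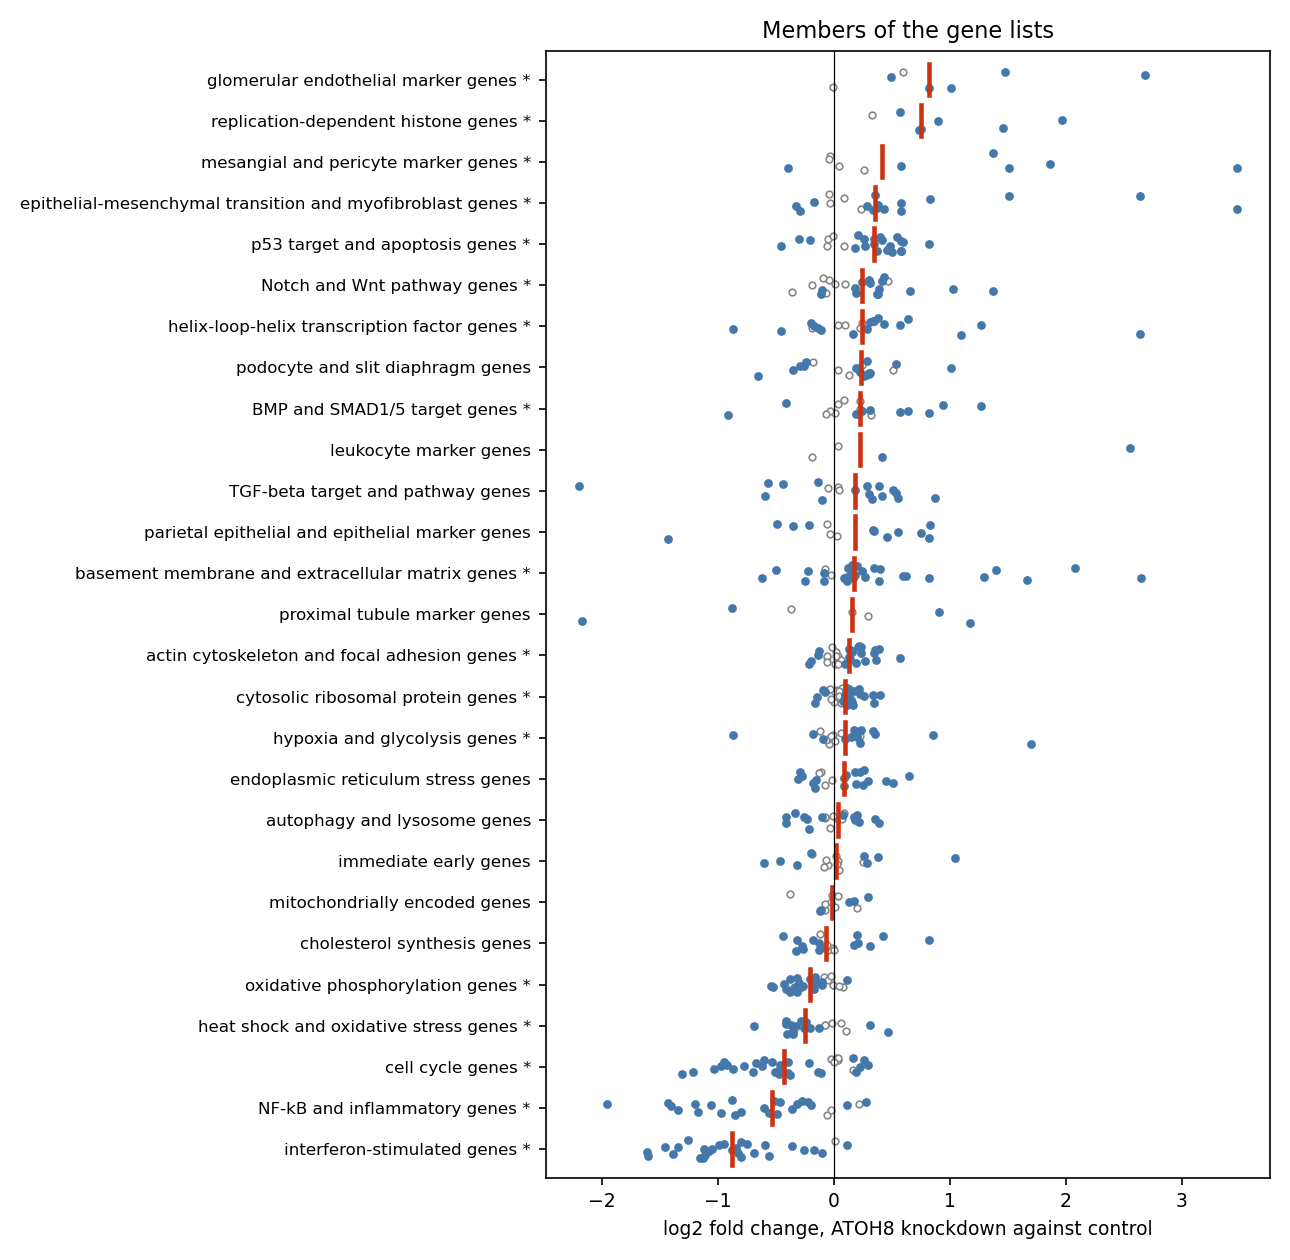
Log2 fold change of ATOH8 knockdown against control (horizontal axis) for each tested member of the 27 gene lists (rows), with filled blue points for genes past the threshold, open grey points for the others, a red bar at the median of each list and a star at the 17 lists called by camera. Interferon-stimulated genes had the lowest median, -0.88, and glomerular endothelial markers the highest, 0.82.

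Signalling and transcription factor lists held genes that rose and genes that fell. Of 18 BMP and SMAD target genes, 8 rose, 2 fell and 8 did not pass (median log2 0.23), and adjusted over the list alone 9 rose and 2 fell. ID1 (4.44 ± 0.553 to 10.8 ± 0.858 CPM, log2 1.27), ID3 (log2 0.57, SE 0.053) and SMAD9 (log2 0.83, SE 0.133) rose, and MSX2 (log2 -0.91, SE 0.175) and BAMBI (log2 -0.41, SE 0.087) fell. The camera call stood close to the threshold (adjusted p = 0.0489, and adjusted p = 0.128 with an estimated correlation) and was lost under several alternatives, among them the replicate block (adjusted p = 0.0536) and the omission of control replicate 1 (0.0507), control replicate 2 (0.064), knockdown replicate 3 (0.0631) or knockdown replicate 4 (0.0716). Of 23 helix-loop-helix transcription factor genes, the family of ATOH8, 12 rose, 6 fell and 5 did not pass (median 0.24, camera adjusted p = 0.0423, but adjusted p = 0.104 with an estimated correlation and 0.06 without control replicate 2), and adjusted over the list alone 13 rose and 6 fell. EPAS1, a hypoxia-inducible factor, rose (log2 0.43, SE 0.034) and MSC (log2 -0.87, SE 0.074), TCF4 (log2 -0.46, SE 0.049) and MYC (log2 -0.20, SE 0.050) fell. Of 23 Notch and Wnt pathway genes, 13 rose, 2 fell and 8 did not pass (camera adjusted p = 0.00801, but adjusted p = 0.104 with an estimated correlation). The rises included DKK3 (log2 0.37, SE 0.031), the receptor NOTCH3 and the transcription factor TCF7 (log2 0.42, SE 0.046). The falls were those of NOTCH2 (log2 -0.11, SE 0.033) and WNT5A (log2 -0.11, SE 0.034). Of 19 TGF-beta target and pathway genes, 10 rose and 6 fell, and camera did not call the list (adjusted p = 0.772). LTBP1 (log2 0.87, SE 0.051), LTBP2 (log2 0.56, SE 0.034) and TGFBR2 (log2 0.54, SE 0.035) rose, while TGFBR1, INHBA (log2 -0.59, SE 0.031) and the ligand gene TGFB2 (log2 -0.57, SE 0.034) fell.

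Among lists of metabolic, stress and ribosomal protein genes, some were called lower and others higher. Of 27 nuclear oxidative phosphorylation genes, 20 fell, 1 rose and 6 did not pass (median log2 -0.21, camera adjusted p = 6.41e-06, but adjusted p = 0.104 with an estimated correlation), among them CYCS, which encodes cytochrome c (173 ± 7.01 to 119 ± 2.82 CPM), and the ATP synthase subunit gene ATP5F1C (log2 -0.38, SE 0.036), while UQCRC1 (log2 0.12, SE 0.036) rose. Of 13 mitochondrially encoded genes, 3 rose and 2 fell, with no call (camera adjusted p = 0.881), and adjusted over the list alone 3 rose and 1 fell. Their median log2 change was -0.01, and mean and test pointed up. Of 20 heat shock and oxidative stress genes, 13 fell and 2 rose (median -0.25, camera adjusted p = 7.92e-05, and adjusted p = 0.0328 with an estimated correlation), with the quinone reductase NQO1 (log2 -0.69, SE 0.040), the thioredoxin TXN (log2 -0.42, SE 0.033) and the chaperone HSPH1 (log2 -0.41, SE 0.032) falling and the heme oxygenase HMOX1 (log2 0.46, SE 0.043) and the cystine transporter SLC7A11 (log2 0.31, SE 0.072) rising. Of 23 hypoxia and glycolysis genes, 11 rose and 3 fell (median 0.09, camera adjusted p = 0.0142, but adjusted p = 0.197 with an estimated correlation), with NDRG1 (log2 0.86, SE 0.044), EGLN3 (log2 1.70, SE 0.125) and BNIP3L (log2 0.34, SE 0.033) rising and the glycolytic genes PGK1 (log2 -0.18, SE 0.033), PKM (log2 -0.10, SE 0.031) and ALDOC (log2 -0.87, SE 0.318) falling. The PKM call was lost without knockdown replicate 2, and the ALDOC call in 4 of the 8 fits that left out 1 library, without a filter and by DESeq2. Of 36 cytosolic ribosomal protein genes, 22 rose and 4 fell (median 0.10, camera adjusted p = 0.00625, but adjusted p = 0.574 with an estimated correlation), and adjusted over the list alone 23 rose and 4 fell. RPLP1 (log2 0.40, SE 0.031), RPL4 (log2 0.35, SE 0.032) and RPLP0 (log2 0.34, SE 0.033) were among the rises, and RPS14 (log2 -0.17, SE 0.033), RPL38 (log2 -0.15, SE 0.032) and RPL27 (log2 -0.10, SE 0.032), whose call was lost in 3 of the 8 fits that left out 1 library, among the falls. Ribosomal protein genes have many processed pseudogenes, so their counts depend on how shared reads were assigned.

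The remaining lists were not called by camera. Of 22 endoplasmic reticulum stress genes, 12 rose and 6 fell (adjusted p = 0.578), with HERPUD1 (log2 0.45, SE 0.040) and TRIB3 (log2 0.51, SE 0.046) rising and the chaperone genes HSP90B1 (log2 -0.31, SE 0.031) and HSPA5 (log2 -0.29, SE 0.032) falling, and adjusted over the list alone 12 rose and 8 fell. Of 22 cholesterol synthesis genes, 6 rose and 9 fell (adjusted p = 0.461), and median and mean log2 changes were -0.06 and -0.02. Of 23 autophagy and lysosome genes, 7 rose and 7 fell (adjusted p = 0.881), with a median of 0.04, a mean of -0.01 and a test that pointed down. Of 17 immediate early genes, 4 rose, among them JUN (log2 0.38, SE 0.033), and 4 fell, among them IER3 (log2 -0.46, SE 0.032) and FOSL1 (log2 -0.32, SE 0.036), with no call (adjusted p = 0.772), and adjusted over the list alone 3 rose and 4 fell. Its median and mean were 0.02 each, and the test pointed down. Counts adjusted over the list alone were the same for the Notch and Wnt, TGF-beta, oxidative phosphorylation, heat shock, hypoxia, cholesterol and autophagy lists. In 46 rows of the table, the lowest or the highest library of a group stood at least 5-fold from the nearest other one, with the larger of the pair at a scaled count of at least 40, as in ISY1-RAB43 with 0, 336, 166 and 619 counts in the control libraries, and 32 of these were tested and 1, FAM220A, was called.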

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

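Among 308 groups of 4 libraries, one for each named gene or library measure and group, 16 (5.2%) held a library set apart from the other 3 by more than Dixon's limit for 4 values, and chance sets apart about 5%. The value given with each is the gap to the nearest other library as a share of the range.

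Control replicate 1 accounted for 8 of the 16. It was the highest control library for FAM220A (0.899, 9.41 CPM against at most 0.95), KIRREL1 (0.862, 653 against 615 to 620 CPM), FOSL1 (0.848), the mitochondrially encoded genes MT-ND4 (0.894, 6389 against 5325 to 5438 CPM) and MT-CO3 (0.882), and for the percent of counts on the top 10 genes (0.853, 8.91 against 8.16 to 8.27). It was the lowest control library for SAGSIN1 (0.842, 7.05 against 15.6 to 17.2 CPM) and CLDN2 (0.882). Control replicate 3 was the lowest for NID2 (0.858) and VCAM1 (0.881).

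In the knockdown group, replicate 2 was the lowest for CDH11 (0.92) and CDKN1A (0.96, 1414 against 1484 to 1487 CPM). Replicate 4 was the highest for CYCS (0.876), MYC (0.882) and H1-2 (0.893, 13.9 against 11.4 to 11.7 CPM), and the lowest for IER3 (0.862). Of these genes, FAM220A and MT-CO3 lost their calls under some alternatives.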

How the results depend on the processing

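One test here was chosen after the data were seen, the one without the 977 genes whose 3′ UTR holds the heptamer GTCAATT. ATOH8 stayed lower and past the threshold under every alternative run, with log2 changes of -1.34 to -1.20 when single libraries were left out. Genes higher ran from 3951 to 4167, genes lower from 4084 to 4299 and genes changed at least 2-fold from 795 to 868 without 1 library. Without a filter on low counts 1481 genes changed at least 2-fold and with a stricter filter 476, since genes with low counts enter or leave the test. All 149 other named genes kept their direction under every alternative that tested them, and 139 kept their side of the threshold, the exceptions being FAM220A, IRF9, PKM, ALDOC, FOS, RPL27, MT-CO1, MT-ND5, MT-CO3 and CUBN. Scalings moved the median of all genes by less than 0.1 (log2).

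Any pairing of the libraries by replicate number was weak, since the same-number correlations of deviations ran from 0.001 to 0.057. A weak pairing is not excluded, because 6 of 8 libraries correlated best with their own number. With the replicate block 4336 genes were higher, 4466 lower and 762 changed at least 2-fold, and ATOH8 was at -1.26.

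With an estimated correlation 5 of 17 lists stayed called. The lost calls had adjusted p = 0.104 (actin, basement membrane, interferon, oxidative phosphorylation, Notch and Wnt, helix-loop-helix), 0.064 (cell cycle, endothelial), 0.0978 (histone), 0.128 (BMP), 0.197 (hypoxia) and 0.574 (ribosomal). The BMP list was also lost with DESeq2 size factors (0.05), the stricter filter (0.0592), the replicate block (0.0536), without heptamer genes (0.0714) and without shared members (0.352), and ran from 0.0354 to 0.0716 without 1 library. The helix-loop-helix list was lost with the stricter filter (0.0792) and without shared members (0.432), and ran from 0.0328 to 0.06 without 1 library, and the transition list was lost without shared members (0.0992). With fry, which does not compare a list with other genes, the podocyte (0.00147), endoplasmic reticulum stress (0.0329), cholesterol (0.00263), parietal (0.000317) and proximal tubule (0.00931) lists passed. The parietal list also passed without shared members (0.00556) and ran from 0.0354 to 0.257 without 1 library, and the TGF-beta list passed, higher, without heptamer genes (0.000198), which decides nothing, since the heptamer was chosen because its carriers, TGFBR1 among them, fell in these data. Uncalled lists changed direction for mitochondrially encoded genes without a filter (0.99) and without 1 library (0.159 to 0.988), and for autophagy genes without 1 library (0.723 to 0.957). The cause was not tested for these. The pseudocount, value filter and scaling alternatives for normalized values were not run because the table holds counts, and DESeq2 gives no list test.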

Other observations

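All tests in this part other than those on splits of the libraries were chosen after the fold changes had been seen, and so were the genes in the first 2 paragraphs.

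Of genes of class I antigen presentation, grouped after their falls had been seen and without a list test, all 14 examined passed the test per gene and were lower in ATOH8 knockdown, with a median log2 change of -0.38. HLA-B went from 2078 ± 57.0 to 1042 ± 55.2 CPM (SD, n = 4) and HLA-C from 1083 ± 24.6 to 662 ± 41.6 CPM (log2 -0.71). The immunoproteasome subunit PSMB9 (log2 -0.91, SE 0.048), the peptide transporter TAP2 (log2 -0.41, SE 0.035) and the light chain B2M (log2 -0.23, SE 0.037) fell as well. Class I genes share sequence, so the counts of HLA-B and HLA-C depend on how shared reads were assigned, a limit that concerns PSMB9, TAP2 and B2M less.

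Type IV collagen chains divided by type. The widely expressed chains COL4A1 (1195 ± 29.6 to 1357 ± 26.1 CPM, log2 0.18) and COL4A2 (log2 0.16, SE 0.035) rose, while COL4A3 (log2 -0.62, SE 0.167), COL4A4 (log2 -0.50, SE 0.069) and COL4A5 (log2 -0.25, SE 0.047), the chains of the mature glomerular basement membrane, fell, and COL4A6 had a log2 change of -0.37 (SE 0.3) that did not pass. Among 9 claudins, CLDN11, CLDN4 (log2 0.76, SE 0.044) and CLDN15 (log2 0.48, SE 0.124) rose and CLDN2 and CLDN12 (log2 -0.28, SE 0.039) fell. All 4 keratins of simple epithelium rose, with KRT18 at log2 0.35 (SE 0.035) and KRT7 at 0.34 (SE 0.054). The aldo-keto reductases AKR1B1 (1225 ± 33.6 to 787 ± 34.8 CPM) and AKR1C3 (log2 -1.33, SE 0.107) fell. The imprinted genes IGF2 (0.184 ± 0.089 to 2.23 ± 0.536 CPM), MEG3 and MEG8 (0.146 ± 0.071 to 1.03 ± 0.256 CPM) rose. Only these 3 imprinted genes were picked out, so this does not describe imprinted genes as a class.

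Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many genes higher (4253, against at most 1 in any other split). The same held for genes lower (4372, against at most 1) and for genes changed at least 2-fold (757, against at most 1). A share of 1 in 35 is the smallest that these splits allow. Every other split mixes the groups, so any difference between them adds to the spread within its sides and lowers its counts. The splits therefore do not exclude chance for these counts. For the gene list tests 2 of the 35 splits gave as many called lists, the real one with 17 and another with 17. That other split had 3 libraries of a group on one side, so it kept part of the difference between the groups. For that count, too, the splits cannot decide on chance and do not exclude it. The 16 splits with 3 libraries of a group on one side called 8 to 17 lists, and the 18 splits with 2 libraries of each group on either side called at most 3, so the number of calls follows how far a split parts the groups.

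Genes whose 3′ UTR holds the heptamer GTCAATT fell as a class. Of 16247 words of 7 bases tested in 12937 autosomal genes, it had the lowest z, -8.76. UTR length, GC content and expression were in that model, which argues against these trends, as modelled, as the whole cause. The lowest z with shuffled fold changes was -3.75, but shuffling also removes any trend that the model missed. In the other direction the word TTTTCAT reached a z of 4.76, so the shuffled limit is too narrow. Found on the odd chromosomes alone, GTCAATT ranked 1 on the even chromosomes. There, with those trends removed from fold changes limited to a log2 size of 2, 441 genes with it averaged -0.103 (log2) from the 5239 without it (permutation p = 1e-05, the smallest that 100000 permutations can give). Of 241 genes with the octamer GTCAATTA 55.6% fell and 13.7% rose, of 691 with the heptamer only 44.9% fell and 22.6% rose, and of 12005 without a site 27.7% fell and 29.2% rose. These percentages are not adjusted for UTR length, GC content or expression. At least 2-fold, 11 octamer genes fell and 1 rose, 8 genes with the heptamer only fell and 21 rose, and 124 without a site fell and 405 rose. ATOH8 itself holds the heptamer in its coding sequence, at bases 875 to 881 of transcript ATOH8-201 in GENCODE release 29 (context GTTCCTACTCGTCAATTTCACACGTAA), as it holds 12.7% of all such words, so a candidate explanation is that the knockdown shRNA targets this stretch and its seed pairs with other 3′ UTRs, TGFBR1 with 4 sites among them, although no other of the 10 largest falls with a searched 3′ UTR holds the heptamer. Whether loss of ATOH8 itself (log2 -1.26) contributes cannot be told apart, because the libraries are not labelled by shRNA sequence and no comparison between shRNAs against ATOH8 was made here.

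Interferon-stimulated and NF-kB genes fell, and 4 of the 29 and 2 of the 26 members hold the heptamer. The tables argue against pairing in their own 3′ UTRs as the whole cause, since the medians hardly moved without the members that hold it. The interferon-stimulated members without it had a median log2 change of -0.84 (SE of the mean 0.095), against -0.88 for all. The NF-kB members without it had one of -0.52 (SE 0.12), against -0.54 for all. These SEs treat members as independent and may be too small, since the estimated correlations were 0.543 and 0.237. The median difference of -0.88 (log2) over the interferon-stimulated genes could also come from a rise in the control libraries caused by the control construct, and this cannot be told apart from a fall in knockdown because no untransfected cells were analysed here. Loss of ATOH8 stays open and was not tested.

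Genes of chromosomes 14 and 15 were higher along the whole chromosome, with median log2 changes of 0.16 over 409 genes and 0.18 over 402 genes, while chromosomes 13 (-0.17) and 5 (-0.16) were lower. With trends in GC content, transcript length and expression removed, chromosome 15 stayed at 0.177 and chromosome 14 at 0.198, above the 0.05 that the largest chromosome median of shuffled data reached at its 95th percentile, which argues against these trends as their cause, while chromosome 13 moved to -0.088 and chromosome 5 to -0.102. The medians of 13 of 22 chromosomes lay beyond that limit. Shuffling treats genes as independent, so passing the limit does not by itself show that a whole chromosome shifted. On chromosome 2, which passed with a median of -0.067, 38.7% of the windows of 31 genes had a median above 0 after the trends were removed. On chromosome 13 that share was 0% and on chromosome 5 it was 0.4%. A difference in the number of copies of these chromosomes in part of the cells would shift every stretch alike, and 100% of the windows of 31 genes on chromosomes 14 and 15 had a median above 0 after the trends were removed, but so did 100% of those on chromosomes 18 and 21, whose medians were 0.063 and 0.08. A difference in copies cannot be told apart from other causes, because DNA was not analysed here, nor can groups grown from different cell stocks, which would bear on the reading of every gene called, and an effect of ATOH8 loss on these chromosomes was not tested.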
